A study of Mus musculus with 12 samples.

How the data were processed

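ATAC-seq libraries were made from naive, Th1 and Th2 CD4+ T cells of mice, wild type or with a knockout of a super-enhancer of Ets1. Per the labels' protocols, naive cells were taken from the spleen with negative selection beads after red cells had been lysed, part of them was polarized in culture for 6 days, and purity was checked by flow cytometry. Reads were aligned with BWA to GRCm38, handled with Picard and made into peaks with MACS2, per the submitters' processing notes, and their versions and settings are not given in the sources used here. Each of the 12 deposited files was the peak list of 1 library in 9 columns. Per the layout of the deposited lists, the values per peak are a score, a fold enrichment (ratio) over the caller's local background, and the −log10 of the p-value and of the q-value. The deposited score was 10 times the −log10 q-value, without its decimals, in every list, and the highest q-value was near 0.1. The column set without a summit is that of the broad mode of MACS2. These values are scaled within a library by the authors' peak calling, so scores were used to rank peaks within a list and never compared between lists.

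The number of reads behind each list is unknown, so no interval from counting error could be given and an absent peak means only that none was called. Median peak width was 387 to 420 bp, with 200 bp as the shortest, and the peaks covered 16.5 to 26.4 Mb per library. The median −log10 q-value was 8.21 and 9.78 in naive wild-type lists, 4.93 and 5.68 in naive knockout lists and 3.39 to 4.14 in the other lists, with median fold enrichments of 3.96 to 5.10.

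Peaks on chromosomes 1 to 19 and X were used, and those on Y and on mitochondrial DNA were left out. Overlapping peaks (at least 1 bp) of all libraries were merged into 110642 regions with a median width of 450 bp, and a library has a region where 1 of its peaks overlaps it. Groups followed the labels, with 2 libraries per group. Of the knockout libraries titled Th1, 2 have Th2 cells as their source name and were taken as Th2 knockout. Lost, gained and cell-type-specific regions were counted as presence in both libraries of a group and absence from both of the other, beside the 2 other splits of the same 4 libraries. For the 8 polarized libraries all 35 splits into 4 and 4 were counted. Overlaps of lost or gained regions between cell types were set beside the number that independent lists would share. For this, lists were cut to regions with a peak in every library in which a shared call requires one. For regions lost in Th1 and Th2 cells these were 486 and 253 calls among 26049 regions. No p-value per region was computed, since an exact test of 2 against 2 cannot go below 0.333.

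Gene positions came from the GRCm38.p6 gene table, which held all 175 genes of the 14 fixed lists. A gene's regions are those that overlap its body with 20 kb on each side. The share of a list's open regions that were lost or gained was compared with 10000 random lists of as many protein-coding genes, matched on the number of open regions. For this comparison a region near several genes of a list counted once for each gene, in the random lists too. The printed shares count each region once. The two-sided p from the percentile (0.0002 at the smallest) was adjusted by Benjamini-Hochberg over the lists and comparisons of a family. These p-values describe the libraries at hand, since genes are not replicates, and those of naive cells rest on technical replicates. Retention of lineage-specific regions used sets chosen in 1 replicate and read in libraries not used to choose them. The computations were tested on simulated data of 110642 regions. For a simulated Th1 knockout 172 of 200 planted lost regions were found, where 163 were to be found by the simulated detection rate. Besides the planted ones 1036 regions were called lost there, against 1181 lost in the real Th1 knockout. The simulated detection rates were means over wild-type and knockout Th1 libraries together, so any real loss entered them. Such calls can arise from detection alone, but the simulation cannot show what share of the real ones does. A planted stretch of 6 regions ranked first, retention without an effect was -0.0423 points, and 3 of 100 null gene lists had a p under 0.05. The retention simulation gave all libraries of a cell type the same detection rates, so it does not cover lists of unequal length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

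The groups, the comparisons, the 14 gene lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those named here as added. Named are Ets1, Fli1 and the genes within 1 Mb of Ets1, the 4 members of each fixed list with most lost or gained regions in a comparison, and the 10 protein-coding genes with most regions per knockout comparison and direction. From these the text gives the genes with a known role and a summary of the rest, and results at some of the genes are not reported here. Genes outside the rule are marked as chosen after their values were seen. The B cell genes Ms4a1 and Cd22 were named after their values were seen, and so were Gm27162, Xist, the Y-linked genes, the antigen receptor genes and the erythroid list.

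The alternatives were the same number of peaks from each library (the 34746 with the highest score), the upper 50% of each list, peaks that cover at least 50% of a region, merging of peaks within 500 bp, regions with a peak in at least 2 libraries, each replicate left out in turn, grouping by title, a replicate block for Th1 and Th2, gene windows of 50 kb, and a minimum of 3 or 6 wild-type libraries in the scan for runs. Added after the data were seen were the ranking of stretches between knockout peaks, counts without chromosome X, list tests for gained, cell-type-specific and naive-only regions, sets chosen in a knockout replicate, splits with 2 Th1 and 2 Th2 libraries on each side, other forms of the test of a general loss of peaks, and the erythroid list. Motif tests were left out because no genome sequence was at hand, and windows at transcription start sites because the gene table gives no strand.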

Results

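Open chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in mouse CD4+ T cells from the spleen. The cells came from wild-type C57BL/6J mice and from mice labelled as a knockout of a super-enhancer (a cluster of enhancers) of Ets1. Naive cells were compared with cells polarized for 6 days to Th1, the interferon-gamma producing helper type, or to Th2, the type that produces IL-4, IL-5 and IL-13. This made 6 groups of 2 libraries each. The naive libraries were technical replicates of 1 biological sample per genotype, so their spread is technical, whereas the Th1 and Th2 groups held 2 biological replicates each by their titles, for Th2 knockout on conflicting labels. The deposited files were lists of called peaks, so the sequencing depth of each library is unknown. The lists held 52571 and 56195 peaks in naive wild-type cells and 41075 and 43823 in naive knockout cells. Th1 wild-type libraries had 44223 and 34746 peaks, Th1 knockout 46006 and 44372, Th2 wild-type 54160 and 51600, and Th2 knockout 56357 and 52561. The merged lists gave 110642 regions, of which 14561 had a peak in every library. A region is called lost where both wild-type and neither knockout library had a peak, and gained in the reverse case.

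The targeted locus was examined first, as a check of the genotype labels. Ets1 (NCBI gene 23871), which encodes an ETS transcription factor needed for T cell development and Th1 responses, lies at 32636241 to 32757820 on chromosome 9 (GRCm38). A stretch of 30.6 kb that starts 140.0 kb beyond the end of Ets1, from 32897838 to 32928447, held 32 peaks of the 6 wild-type libraries and no peak of the 6 knockout libraries. Naive wild-type libraries had 6 and 6 peaks there, Th1 wild-type 5 and 4, and Th2 wild-type 6 and 5. The stretch overlaps Gm27162, a long non-coding RNA gene at 32904069 to 32928966 that was chosen after its values were seen. The regions 32915558 to 32916118 and 32925907 to 32926705 had a peak in all 6 wild-type libraries.

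Among 16427 stretches of the genome that lay between neighbouring knockout peaks and held wild-type peaks, this was the one with most, ahead of a stretch with 13 peaks in the T cell receptor alpha variable genes on chromosome 14 (53614667 to 53683482). That ranking was chosen after the data were seen. The planned scan asked for runs of consecutive regions, each with a peak in at least 4 wild-type and no knockout libraries, and 179 regions met this. The longest runs were 2 regions long, and both lay in the stretch beyond Ets1, at 32910331 to 32916118 and 32924481 to 32926705. With the same number of peaks from each library, the longest run grew to 5 regions (32910331 to 32929031), and no other run was longer than 1. At the far edge, the region 32928294 to 32929031 had a peak in all wild-type and in both naive knockout libraries, where its score stood at percentiles 9.63 and 4.00 of the list against 98.5 and 98.2 in the naive wild-type lists.

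**Figure D1:**
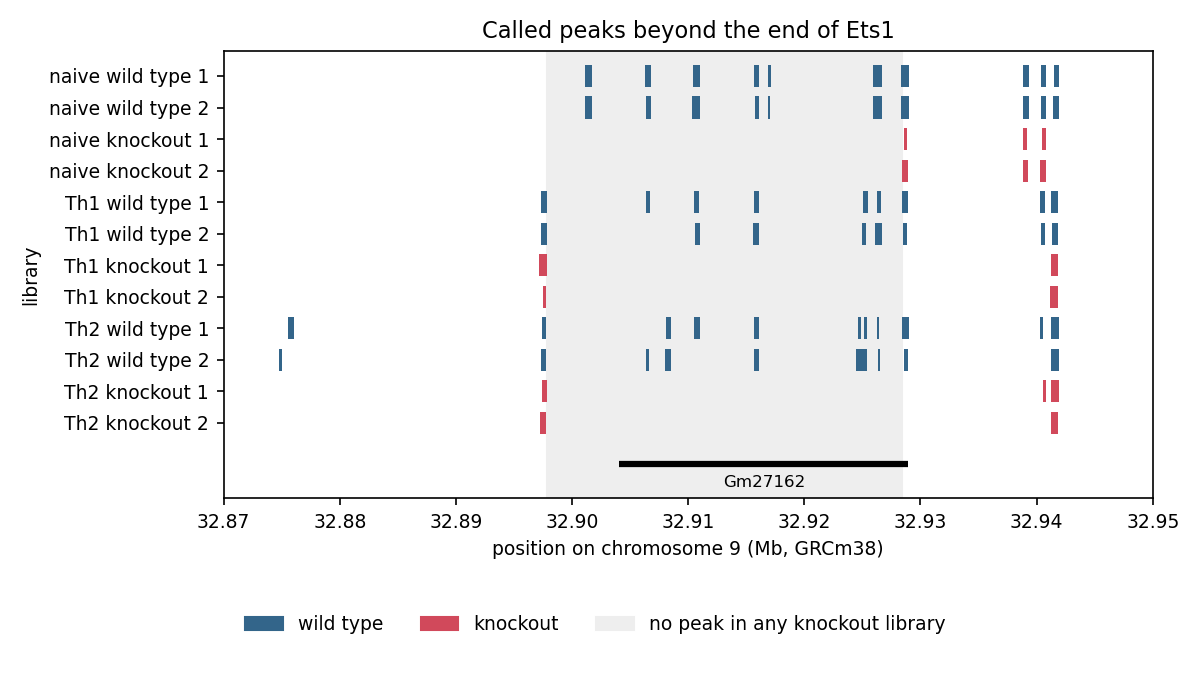
Called peaks (boxes) of the 12 libraries, in the order of the rows, against position on chromosome 9 in Mb (GRCm38), blue for wild type and red for knockout, with the stretch without knockout peaks shaded and Gm27162 drawn as a bar. The shaded stretch holds 32 wild-type peaks, and peaks of both genotypes flank it.

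At Ets1 itself, the gene with 20 kb on each side had peaks in 30 and 28 regions in naive wild-type libraries and in 16 and 20 in naive knockout libraries, with 8 regions lost and 2 gained. That difference shrank to 3 lost and 3 gained with the same number of peaks from each library. In Th1 cells 1 region was lost there (32759448 to 32760090) and in Th2 cells another (32738478 to 32738941), and none was gained. Fli1, the neighbouring ETS factor gene, had 2 regions lost and 2 gained in naive cells, 1 lost and 1 gained in Th1 cells, and 1 gained in Th2 cells. Kcnj1, a potassium channel gene, had 1 region lost in Th1 cells, and Barx2, a homeobox gene, gained 1 in Th1 and 1 in Th2 cells. Kcnj5, another channel gene within 1 Mb of Ets1, had no lost or gained region in the 3 cell types.

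In naive knockout cells, regions were lost at several T cell genes, though no gene list passed its test for lost regions. Fyn, a Src-family kinase of the T cell receptor, had 15 of 49 regions lost and none gained, and Syne1, a nuclear envelope gene, had 18 of 43 lost. The 49 and 43 are regions with a peak in any library. Naive wild-type libraries had peaks in 32 and 33 regions of Fyn and in 28 and 28 of Syne1. The naive T cell regulators Bach2, Foxp1 and Foxo1 had 11, 9 and 5 lost regions, against 1, 3 and 0 gained. In the naive wild-type libraries Bach2 had peaks in 45 and 46 regions, Foxp1 in 66 and 65 and Foxo1 in 17 and 17. Bcl11b, which holds T cell identity, had 3 lost, Foxp3, the regulatory T cell factor, 4, and Rora, a nuclear receptor of Th17 cells, 10. Their regions with a peak in the naive wild-type libraries were 16 and 22, 7 and 9, and 23 and 27. Naming by the number of lost regions favours genes with many regions. Of all regions open in both naive wild-type libraries 20.9% were lost, and no single gene was tested against that share. Among the genes with gained regions, Pax5, the B cell identity factor, gained 3 regions, and Cd79b, a B cell receptor chain, 4 with 1 lost. Hbb-bh1, an embryonic beta-globin gene, gained 4 of its 4 regions, counted with 20 kb on each side, where a region can belong to a neighbouring gene. Ttc39a, a gene of unknown function in T cells, and Rftn1, a lipid raft gene of B cells, gained 6 each. Rftn1 had peaks in 15 and 18 regions in naive wild-type and in 19 and 21 in naive knockout libraries.

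Over the genome 9794 regions were lost and 3019 gained in naive knockout cells, which is 20.9% and 8.67% of the regions open in both libraries of the respective genotype. The same count over the 2 other splits of these 4 libraries gave totals of 868 and 801, so the split by genotype separated 14.8 times as many regions as the highest other. These other splits exchange technical replicates of 1 sample per genotype, so they show technical spread only. The ratio measures no spread between animals and cannot be set against those of Th1 and Th2 cells. The naive wild-type libraries had peaks at 4 of 4 Y-linked genes and the naive knockout libraries at 0 of 4 (genes chosen after their values were seen), so by these genes genotype appears confounded with the sex of the animals in naive cells. Xist, the X inactivation gene, with 1 kb on each side had 2 and 2 peaks in naive wild-type and 3 and 3 in naive knockout libraries, 0 in all Th1 libraries and at most 1 in Th2 libraries, so it does not settle the sex. With 2 libraries against 2, an exact permutation test cannot give a p below 0.333. The knockout lists were shorter (42449 ± 1943 against 54383 ± 2563 peaks, SD, n = 2 technical replicates). With 34746 peaks from each library, which balances both counts by construction, 3864 regions were lost and 3729 gained, and the total was still 10.1 times the highest other split. Fyn then had 5 lost regions, Syne1 8, Bach2 4, Foxp1 4 and Foxo1 4, with 2 gained at Bach2, 3 at Foxp1 and 1 at Foxo1. Of the 9794 lost regions 24.6% were also lost with equal lists, as were 57.4% of the gained ones. Lost regions were weak calls in the wild type, with median score percentiles of 26.2 and 30.5 against 69.7 and 71.4 for regions open in all 4 libraries. Gained regions were weak calls in the knockout too, at 31.4 and 34.2 against 61.5 and 64.0.

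**Figure D2:**
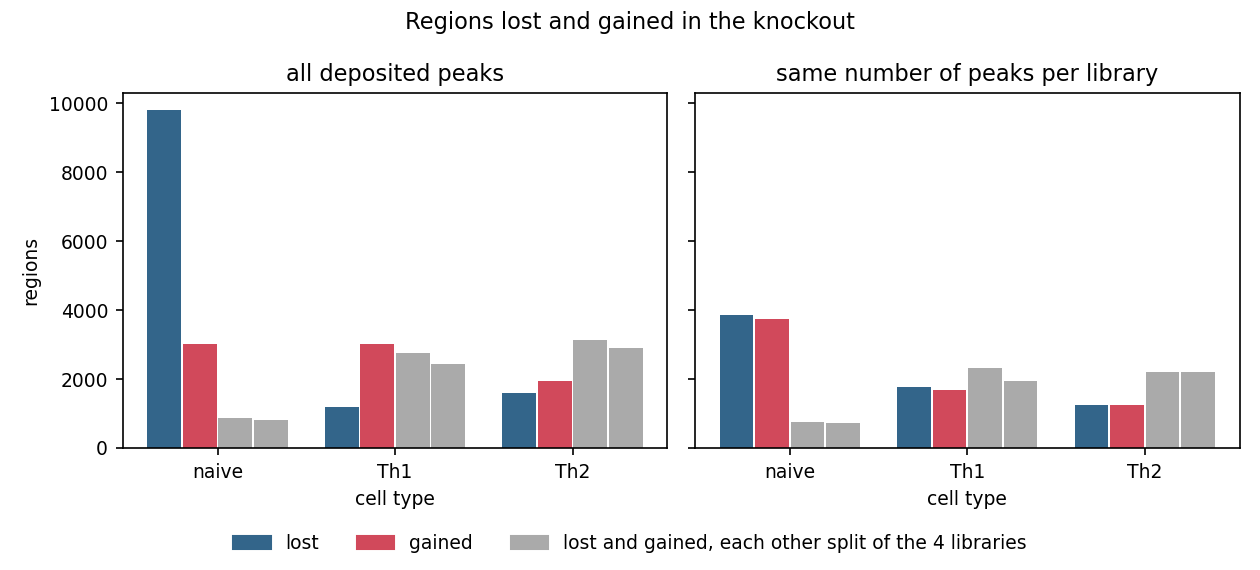
Number of regions lost (blue) and gained (red) in knockout cells of each type, with the totals of the other splits of the same libraries (grey), for the deposited lists and for lists of equal length. In naive cells the genotype totals exceed the other splits with either kind of list, and lists of equal length balance lost and gained counts by construction. The other splits of naive cells exchange technical replicates, so their totals show technical spread only, unlike those of Th1 and Th2 cells.

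By gene list, the B cell genes stood apart among the gained regions of naive knockout cells. Of the 35 regions open in both knockout libraries near 9 B cell genes 15 were gained (42.9%), against a median of 6.25% in random gene lists, and 8 genes had at least 1 (two-sided p 0.0002, the smallest the 10000 random lists allow, adjusted p 0.0084 over 42 tests). The gained regions included 2 at Ms4a1, which encodes CD20 (chromosome 19, 11244263 to 11244689 and 11265979 to 11266858). Ms4a1 had no peak in naive wild-type cells. The 15 gained regions had median score percentiles of 39.9 and 33.3 in the knockout lists. With equal lists the share was 53.6%. The remaining lists did not pass for gained regions in naive, Th1 or Th2 cells, where 5 of the 42 tests had an unadjusted p under 0.05. These included T cell identity genes in naive cells, with 1.03% gained (adjusted p 0.126), and Th17 genes, with 24.0%, of which Ccr6, a chemokine receptor gene, gained 3 (adjusted p 0.274). The Th2 genes had 1.19% gained in Th1 knockout cells (adjusted p 0.284), and the CD8 and NK genes 18.8% in Th2 knockout cells (adjusted p 0.368).

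For lost regions none of the 42 tests passed, with 1 unadjusted p under 0.05, that of the myeloid genes in naive cells (36.4% lost, adjusted p 0.638), with 3 lost regions at Irf8, a myeloid and lymphoid factor gene, and 3 at the integrin gene Itgam. The naive lost shares of T cell lists lay near the 20.9% of all regions: 20.8% for Th1 genes, 21% for Th2 genes (21 of 100), 21.4% for naive and memory T genes, 21.1% for T cell identity genes and 21.2% for ETS family genes. Th17 genes had 34.1% lost, regulatory T cell genes 23.8%, follicular helper genes 15.0%, CD8 and NK genes 15.4% and B cell genes 16.7%. The IL-2 and cell cycle genes had 14.5% lost, housekeeping genes 18.0%, and CTCF and cohesin genes 21.6%. For naive gained regions the shares were 5.06% for Th1 genes, 5.41% for Th2 genes, 3.05% for naive and memory T genes, 7.48% for ETS family genes, 16.0% for myeloid genes, 11.8% for IL-2 and cell cycle genes and 2.86% for housekeeping genes. Regulatory T cell, follicular helper, CD8 and NK, and CTCF and cohesin genes had 0 gained regions in naive cells.

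**Figure D3:**
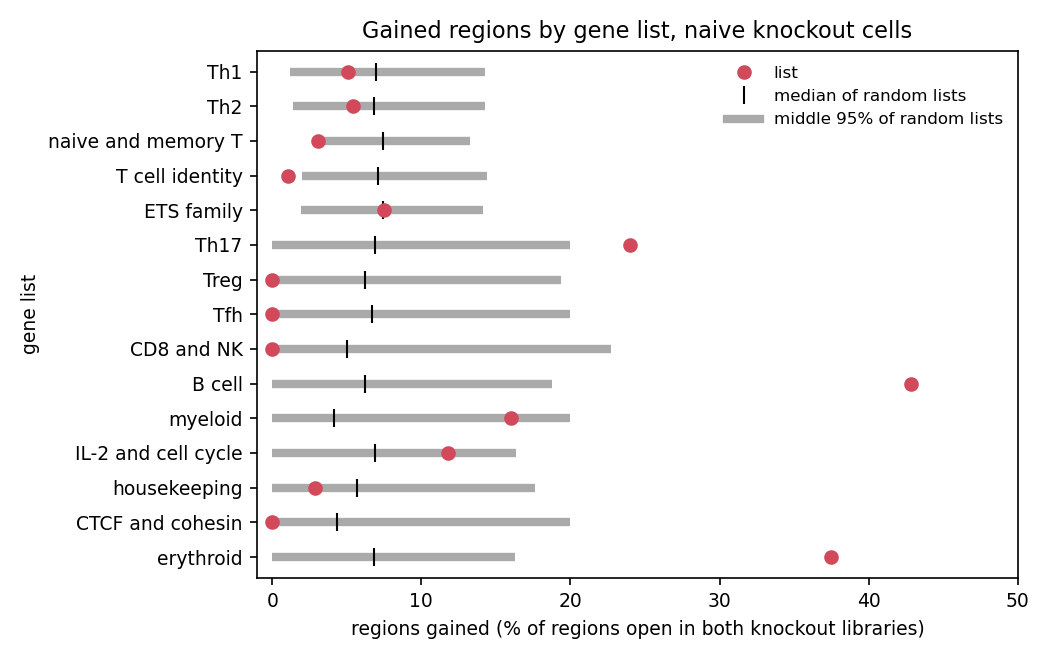
Percent of regions open in both naive knockout libraries that were gained, per gene list (dots), with the middle 95% of random gene lists matched on region number (grey bars) and their median (ticks). The B cell list at 42.9%, the erythroid list, which was chosen after the data were seen, and the Th17 list lie above their bars, and the T cell identity list lies below its bar.

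In Th1 knockout cells few regions at Th1 genes differed. Ifng, the gene of interferon gamma, and Tbx21, the Th1 master regulator, had no lost or gained region (named for this after their values were seen). Il18rap, an IL-18 receptor chain gene, gained 2 regions, and Il12rb2, an IL-12 receptor chain gene, 1, whereas Il12rb1, the other chain, and Fasl, a death ligand gene, lost 1 each. Satb1, a chromatin organiser of T cells, had 2 regions lost and Foxp1 4 gained. Among all genes, Cask, a scaffold kinase gene, and Pcca, a mitochondrial carboxylase gene, gained 6 each, and Vav3, an exchange factor of lymphocyte signalling, 5, while Map3k5, Ptk2b, a kinase gene of leukocyte adhesion, and Nfia had 3 lost each. Genome-wide 1181 regions were lost and 3016 gained in Th1 knockout cells, a total of 4197 against 2754 and 2444 for the other splits of the 4 libraries. The total was 1.52 times the highest other split, and no exact permutation p below 0.333 was possible. In the simulated Th1 knockout 1036 regions were called lost besides the planted ones. Its detection rates came from both genotypes together, so this is not the number to be seen without a knockout effect. Equal lists, which balance both counts by construction, gave 1774 lost and 1694 gained. The direction of the surplus turned without Th1 wild-type replicate 2, the shortest list, with 5698 lost and 4026 gained.

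At the lists of fixed genes, Th1 knockout cells had 3.41% of open regions lost near Th1 genes (3 of 88), 7.06% near Th2 genes (6 of 85) and 4.49% near ETS family genes, with no list past its test. Ecm1, an extracellular matrix gene of Th2 cells, lost 1 region, and so did Il10, the gene of an anti-inflammatory cytokine. In gained regions the shares were 5.43% for Th1 genes, 6.72% for naive and memory T genes and 3.23% for ETS family genes.

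In Th2 knockout cells the differences at Th2 genes were as few. Il4ra, the IL-4 receptor gene, had 2 regions lost, while Il1rl1, the IL-33 receptor gene, Epas1 and Ecm1 gained 1 each. Gata3, the Th2 master regulator, and the cytokine genes Il4, Il5 and Il13 had no lost or gained region (likewise named after their values were seen). Runx3, a factor of Th1 cells, Il2ra, the IL-2 receptor alpha chain gene, and Etv6, an ETS repressor gene, had 2 lost each. St6gal1, a sialyltransferase gene of lymphocytes, had 4 lost and Cd6, a T cell adhesion receptor gene, 3, whereas Tox, a T cell development factor, and Jazf1 gained 4 each, and Cd28, the co-stimulatory receptor gene, 2. The genome held 1607 lost and 1951 gained regions, a total of 3558 against 3138 and 2907 for the other splits of the 4 libraries (1.13 times the highest). With equal lists 1257 regions were lost and 1259 gained, and 10.5% of the lost and 8.97% of the gained regions were the same ones as before. Near Th2 genes 1.59% of open regions were lost (2 of 126) and 2.42% gained, near Th1 genes 6.98% lost (6 of 86) and 3.75% gained, and none of these lists passed its test. The median score percentiles of lost regions in the wild-type lists were 22.6 and 20.5, and those of gained regions in the knockout lists 21.5 and 21.8.

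Regions that differed in both Th1 and Th2 knockout cells were 55 lost in both, where independent lists would share 4.72, and 86 gained in both, where they would share 14.6. Opposite directions were also shared beyond that number, 79 against 15.5, and these comparisons had no library in common. Naive and Th1 cells shared 131 regions in the same direction (32.3 for independent lists) and 85 in opposite directions (32.6). Naive and Th2 cells shared 145 (40.8) and 93 (35.2). With equal lists Th1 and Th2 cells shared 96 regions in the same direction (17.1) and 76 in opposite directions (14.7). Naive and Th1 cells then shared 107 (29.3) and 59 (31.8), and naive and Th2 cells 74 (22.8) and 46 (21.2).

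The wild-type Th1 and Th2 libraries were compared to see the difference made by the polarizing cytokines. Ifng had 2 regions open in Th1 and not in Th2 cells (chromosome 10, 118435194 to 118435853 and 118440619 to 118441327), and Ccl3 and Ccl4, adjacent chemokine genes, shared 2. Pparg, a nuclear receptor gene of Th2 cells, had 5 regions open in Th2 cells alone, such as 115360793 to 115362112 on chromosome 6, and Il4ra and Il5 had 3 each. Klrd1 and Klrk1, lectin receptor genes of NK and CD8 cells, had 2 Th1-only regions each, beside 2 and 1 Th2-only ones, and Il23r, an IL-23 receptor chain gene, had 3 and 0. Bach2 had 6 and Lef1, a factor of naive T cells, 5 Th2-only regions, against 0 and 1 Th1-only ones. Genome-wide 1746 regions were open only in Th1 and 8347 only in Th2 wild-type cells, a total 5.13 times the highest other split (1967). With equal lists these were 3164 and 3822, at 4.44 times. Of regions open in Th1 cells near Th1 genes 12.5% were Th1-only (11 of 88, 10 of 24 genes, adjusted p 0.0448), a call that ended with equal lists (22.8%, adjusted p 0.104). Near CD8 and NK genes 22.2% were Th1-only (4 of 18, adjusted p 0.0448), and this passed with equal lists too (38.9%, adjusted p 0.0336). The tests count a region once per gene, so regions shared by neighbouring genes weigh more in them than in these shares. This holds for the 2 regions of Ccl3 and Ccl4 and for 129599513 to 129600034 on chromosome 6, near both Klrd1 and Klrk1. The Th2 genes had 18.3% Th2-only regions (23 of 126, adjusted p 0.941). These tests were added after the data were seen, and 2 of 28 passed, with 5 at an unadjusted p under 0.05.

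The libraries with conflicting labels, titled Th1 but with Th2 cells as their source, were placed by their source name. Their titles call them technical replicate 2 of the Th1 knockout biological replicates 1 and 2, so their standing as separate biological replicates of Th2 knockout rests on these labels. They had a peak in 79.6% and 73.1% of the Th2-only wild-type regions and in 26.2% and 22.7% of the Th1-only ones. The other knockout libraries titled Th1 had 32.8% and 27.0% of the Th2-only and 60.1% and 63.4% of the Th1-only regions. The mean Jaccard index (shared regions over regions in either library) of the libraries with conflicting labels was 0.680 and 0.679 with Th2 wild-type libraries and 0.529 and 0.543 with Th1 wild-type libraries. For the other knockout libraries titled Th1 it was 0.575 and 0.575 with Th2 and 0.602 and 0.630 with Th1 wild-type libraries. Taken by title instead, as further Th1 knockout libraries, the libraries with conflicting labels left 456 lost and 1432 gained regions in Th1 cells.

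Across both genotypes, 481 regions were open in all 4 Th1 and no Th2 libraries and 2696 in the reverse case. The split by genotype over the same 8 polarized libraries separated 55 lost and 86 gained regions. The direction turned with equal lists (62 lost, 34 gained) and without Th1 wild-type replicate 2 (173 lost, 108 gained).

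Polarization separated more regions than genotype did. Foxp1 had 36 regions open in naive and not in Th1 wild-type cells, Bach2 25, Lef1 16, Tox 16 and Bcl11b 10, with 6, 8, 1, 2 and 0 in the reverse direction. Ets1 itself had 16 naive-only regions and 2 Th1-only ones. Against Th2 cells, Rad50, the gene that carries the Th2 locus control region, had 8 Th2-only regions and no naive-only one, Pparg 9 and 0, Il1rl1 9 and 4, and Il24, a cytokine gene of Th2 cells, 6 and 2. In all 21877 regions were naive-only and 9945 Th1-only (53.2 times the highest other split), and 19704 naive-only and 18471 Th2-only (60.8 times). The naive libraries in these splits are technical replicates. Of regions open in Th2 cells near Th2 genes 58.7% were absent from naive cells (74 of 126, 20 of 24 genes, random median 40.2%, adjusted p 0.0224), the only list of 56 tests to pass, and it passed with equal lists (65.9%, adjusted p 0.0112). The naive and memory T genes had 62.7% naive-only regions against Th1 cells (adjusted p 0.117) and 61.9% against Th2 cells (adjusted p 0.0821). Both passed with equal lists (59.2%, adjusted p 0.0314, and 67.8%, adjusted p 0.0112). With equal lists so did Th2 genes in Th1 cells (51.9%, adjusted p 0.0168; 43.5%, adjusted p 0.0821 before) and CD8 and NK genes in naive against Th2 cells (69.6%, adjusted p 0.0168; 57.7%, adjusted p 0.117 before). These list tests were added after the data were seen, and 10 had an unadjusted p under 0.05.

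Whether knockout cells kept the lineage-specific regions was asked with sets chosen in 1 wild-type replicate and read in the other, held-out replicate and in both knockout libraries. Th1-specific regions had a peak in 46.7% of cases in Th1 knockout libraries and in 45.6% in held-out wild-type libraries, a difference of 1.13 percentage points (SD 8.47 within genotype, over 2 held-out and 4 knockout readings). The 4 knockout readings are 2 libraries each read with 2 sets, so they are not independent. Each SD here pools readings of both sets, so it mixes the difference between sets with that between libraries. With equal lists the sign turned: 46.3% in the knockout against 52.5% in held-out wild type, -6.18 points (SD 3.35), with all 4 readings lower and with -0.909 points in regions shared by Th1 and Th2 cells. With the deposited lists the held-out Th1 wild-type replicates differed, at 34.5% for replicate 2 and 56.6% for replicate 1. Th2-specific regions in Th2 cells differed by 1.36 points (63.1% against 61.8%), and by -0.540 with equal lists (SD 3.17, 3 of 4 readings below). Th2-specific regions were open more often in Th1 knockout than in held-out Th1 wild-type cells, 32.1% against 23.01% (9.09 points, SD 10.8, 4 of 4 readings above). Most of this came from held-out wild-type replicate 2, the shortest list, at 10.5% against 27.8% and 24.4% in the knockout libraries, whereas replicate 1 stood at 35.5% against 39.9% and 36.3%. With equal lists the means were 30.9% against 25.9% (4.93 points, SD 3.97, 4 of 4 above). With Th2-specific sets chosen in a knockout replicate, Th1 wild-type libraries differed from held-out Th1 knockout libraries by -5.64 points (SD 6.27, 3 of 4 readings below), and with equal lists by -0.263 (SD 2.32, 2 of 4 below). Th1-specific regions in Th2 cells differed by 1.65 points, and by -0.544 with equal lists (SD 2.64, 4 of 4 readings below). All 4 readings below is thus not particular to Th1 cells. The smallest p an exact permutation of 2 against 2 libraries allows is 0.333, so none of these differences could pass that test, and no other test was run on them.

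**Figure D4:**
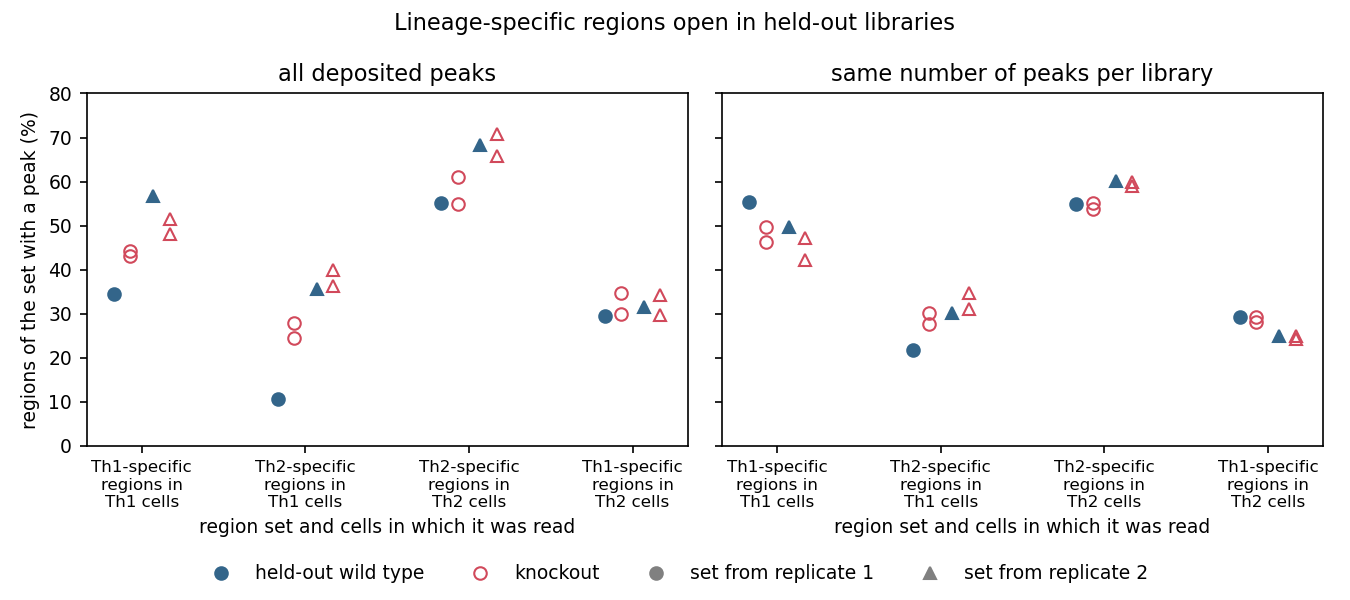
Percent of lineage-specific regions with a peak, in held-out wild-type libraries (filled) and knockout libraries (open), for sets from replicate 1 (circles) and replicate 2 (triangles), with deposited lists and lists of equal length. For Th1-specific regions in Th1 cells, each knockout point lies below the held-out point of its set with equal lists only. The same holds, by smaller differences, for Th1-specific regions in Th2 cells.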

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

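The tests of list length for the naive surplus of lost regions and of a general loss of peaks for the Th1-specific regions were chosen after the results were seen, the second after other forms with equal lists had been tried and found void.

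Naive knockout libraries differed from wild type by -11934 peaks on average, whereas Th1 knockout libraries differed by 5704.5, and in these cell types every knockout library lay on the same side of both wild-type libraries. In Th2 cells the difference was 1579 and the genotypes overlapped. This difference between cell types was not tested. Some regions moved in opposite directions in different cell types, and these differences were not tested either: 31 were lost in Th1 and gained in Th2 knockout cells and 48 the reverse. Between naive and Th1 cells there were 74 lost in naive and gained in Th1 and 11 the reverse, and between naive and Th2 cells 83 and 10.

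More regions were lost than gained in naive knockout cells, at genes such as Fyn, Syne1 and Bach2, and the knockout lists were shorter. List length as the cause cannot be told apart from a wider loss: with the same number of peaks from each library 50.9% of the differing regions were lost, but such lists bring every comparison of 2 against 2 libraries near balance (45.3 to 52.8% in the other 5). Of the lost regions 97.2% lay outside chromosome X, but this cannot decide on a difference in sex between the samples, since losing every X-linked region open in the wild type would still leave 89.2%. What made the knockout lists shorter stays open, as depth is unknown and each genotype is 1 biological sample. That 3864 regions were lost and 3729 gained with equal lists is likewise confounded with the apparent difference in sex and any other between these samples.

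Th1-specific regions were open less often in Th1 knockout than in held-out wild-type cells with equal lists, by -6.18 points (SD 3.35). A general loss of peaks in the knockout libraries was not seen in their number, which was higher by 5704.5 on average, but this rests on 1 short wild-type list and unknown depth, and regions shared by Th1 and Th2 cells differed by 3.55 points (SD 6.28) with the deposited lists, so it stays open. A likeness of libraries of the same genotype, whatever the lineage of the region, cannot be told apart from an effect of the knockout on Th1 regions: sets chosen in a knockout replicate differed by -1.78 points (SD 2.01) in wild type against held-out knockout, between the bounds set for either, and by -10.0 points (SD 7.06, 4 of 4 readings lower) with the deposited lists. The pattern is absent with the deposited lists (1.13 points, SD 8.47), so an effect on Th1 regions is a hypothesis that more replicates of known depth could test.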

How the results depend on the processing

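Counts without chromosome X, and 50 kb windows and equal lists for list tests other than those of regions lost in the knockout, were chosen after the results were seen, and the other alternatives were planned. Of 21 results with a value under each, all 21 stayed within their bounds when peaks had to cover at least 50% of a region, when peaks within 500 bp were merged, and for regions in at least 2 libraries. The same held without chromosome X for both naive counts. With at least 3 wild-type libraries the longest runs were still 2 regions long, but there were 7, also on chromosomes 1, 2 and 6, so the stretch beyond Ets1 no longer stood out. With the upper 50% of each list 4 results did, and with the same number of peaks from each library 9 of 24.

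With the same number of peaks from each library, lost regions moved to 3864 in naive and 1774 in Th1 knockout cells and gained ones to 1694 in Th1 and 1259 in Th2. Th1-only and Th2-only wild-type regions moved to 3164 and 3822, naive-only regions against Th1 to 12240, regions gained over all polarized knockout libraries to 34, and those of all Th1 or all Th2 libraries to 769 and 1224. The run beyond Ets1 grew to 5 regions, and 1 list in place of 2 passed between Th1 and Th2 wild type, that of CD8 and NK genes. Retention reversed to -6.18 points for Th1-specific regions in Th1 cells, -0.540 for Th2-specific ones in Th2 cells and -0.544 for Th1-specific ones in Th2 cells. Lists of unequal length favour absence in the shorter list by construction, and further causes were not tested.

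With the upper 50% of each list every count fell, by construction with fewer peaks. Lost and gained regions were 5148 and 1341 in naive, 588 and 1523 in Th1 and 893 and 1145 in Th2 knockout cells, and 26 and 48 over the polarized libraries. Th1-only and Th2-only regions were 976 and 4522 in wild type and 253 and 1551 over both genotypes. Naive-only and Th1-only regions were 12160 and 5234, naive-only and Th2-only 11407 and 10262, and the run beyond Ets1 had 1 region. It also had 1 where all 6 wild-type libraries had to have a peak, as did each of the 9 runs found. Grouping by title left 456 lost and 1432 gained regions in Th1 knockout cells, by construction with 4 knockout libraries.

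Leaving out 1 library at a time raised the counts by construction, since a region then has to be present or absent in fewer libraries. Naive lost regions ranged from 12226 to 15158 (without wild-type replicate 1) and gained ones from 3509 to 5626 (without knockout replicate 1). Th1 knockout counts ranged from 2390 to 5698 lost (without Th1 wild-type replicate 2) and 4026 to 9268 gained (without Th1 knockout replicate 2), and Th2 counts from 3231 to 6226 lost (without Th2 wild-type replicate 2) and 4160 to 7645 gained (without Th2 knockout replicate 2). Wild-type Th1-only regions ranged from 2748 to 5625 (without Th1 replicate 2) and Th2-only ones from 9690 to 15724 (without Th2 replicate 2). Against naive cells, Th1-only regions ranged from 10334 to 17433 (without Th1 replicate 2), naive-only ones from 23391 to 27749, Th2-only ones from 19043 to 25335 and naive-only ones against Th2 from 22078 to 25140. Over the polarized libraries 82 to 173 regions were lost (without Th1 wild-type replicate 2), 108 to 260 gained (without Th1 knockout replicate 2), 582 to 797 Th1-only (without Th1 wild-type replicate 2) and 2866 to 3697 Th2-only. Without 1 knockout library, retention ranged from 0.0154 to 2.25 points for Th1-specific regions in Th1 cells and from 7.34 to 10.8 for Th2-specific ones in Th1 cells. It reversed without Th2 knockout replicate 1 for Th2-specific regions in Th2 cells (-1.41 to 4.12) and for Th1-specific ones in Th2 cells (-0.728 to 4.03), and the cause was not tested. The run beyond Ets1 had 2 regions in each case.

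The replicate block for Th1 and Th2 wild type gave the same 1746 and 8347 regions, which is so by construction. The replicate numbers share no more than a number, as the deviations of same-numbered libraries correlated at -0.00399 in wild-type and 0.00963 in knockout libraries. Of 180 list tests 175 kept their side of the threshold with 50 kb windows, where 5 were newly passed. With equal lists 175 did as well, 4 were newly passed and the Th1 list was no longer passed. Of 292 counts of lost or gained regions at named genes, 86 were unchanged with equal lists, 187 fell and 19 grew, with 99 at 0. With the upper 50% of each list 46 were unchanged and 240 fell. With covering peaks 193 were unchanged, with merging 260, and with regions in at least 2 libraries all 292. Windows at transcription start sites and motifs were not run. Unknown depth limits every absence: a region lost from a list may be a peak below the calling threshold, the more so as counts moved with list length (3864 against 9794 naive lost regions).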

Other observations

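The tests of B cells and of list length for the B cell genes, the erythroid list, and the splits balanced for cell type were chosen after the results were seen.

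Red cell genes gained regions in naive knockout cells. Near 14 erythroid genes, a list chosen after Hbb-bh1 had been seen and without the beta-globin genes, 15 of 40 open regions were gained (37.5%, random median 6.82%), at 9 genes (two-sided p 0.0002, the smallest the random lists allow, adjusted p 0.0024 over 12 tests). The 15 had median score percentiles of 38.9 and 48.9 in the knockout lists. With equal lists 17 of 37 open regions were gained (45.9%). Slc4a1, the gene of the anion exchanger of red cells, gained 3, Alas2, a haem synthesis gene, 2, and the alpha-globin genes Hba-a1 and Hba-a2 shared 2. Regions were also lost in naive knockout cells at genes of this list, at Tal1, which gained a region too, and at Nfe2. In Th1 knockout cells 0 of 23 open regions of this list were gained, and in Th2 knockout cells 1 of 26.

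The Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y, chosen after their values were seen, had peaks at 4 of 4 genes in naive wild-type and in all Th1 and Th2 libraries, and at 0 of 4 in both naive knockout libraries. Peaks on chromosome Y numbered 22 and 20 in naive wild-type and 10 and 9 in naive knockout libraries. Among the stretches without knockout peaks, the third by wild-type peaks (12 peaks of 5 libraries) lay in the immunoglobulin heavy chain variable genes on chromosome 12, at 114650848 to 114804454. In polarized cells alone the stretch beyond Ets1 held 25 wild-type peaks over 42.7 kb, and the next, at the glycosyltransferase gene Galnt9, held 9.

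The regions gained at B cell genes in naive knockout cells may come from B cells in the naive knockout sample, a hypothesis from a list of 9 marker genes. With equal lists 8 of the 9 had a gained region, and a cause in list length or calling threshold was argued against, since the list's gained share stood at percentile 100 of the random lists. Peaks in the naive wild-type and knockout libraries stood at 3, 3, 5 and 7 regions for Cd79b and 0, 0, 2 and 2 for Ms4a1, but at 6, 6, 5 and 6 for Cd79a, with 1 region gained and 1 lost, and 4, 2, 2 and 3 for Cd22, with none gained from the deposited lists. No gene of the list is in another list (0), and 8 of the 9 have a region in both naive wild-type libraries, counted with 20 kb on each side, where a region can belong to a neighbouring gene. Negative selection beads would remove B cells and flow cytometry would show them, the genotype and the sex of the animals stay open as untested explanations, and each genotype is 1 biological sample.

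Among the 35 splits of the 8 polarized libraries into 4 and 4, 13 separated as many regions as the split by genotype (141 regions, highest other 3177), so over all splits chance cannot be excluded for the regions common to both knockout cell types. The highest of the others was the split into Th1 and Th2 cells, which points to a structure of the samples by cell type. Among the 18 splits with 2 Th1 and 2 Th2 libraries on each side, the split by genotype had the most (141, highest other 116; with equal lists 96 and 86), and 18 splits are too few for a share under 0.05. For Th1 against Th2 cells over both genotypes only the real split, 1 of 35, gave as many (3177 regions, highest other 255). This share is under 0.05 and argues against chance, but it is the smallest that 35 splits allow. It also rests on 2 libraries placed as Th2 on conflicting labels.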
